A study of Mus musculus with 6 samples.

How the data were processed

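RNA from mouse embryonic fibroblasts (MEFs), primary connective-tissue cells grown out of embryos, was sequenced in 6 libraries. Per the labels, the cells were untreated, total RNA was extracted with a column kit, and each library came from a wild-type (WT) or a knockout (KO) culture at passage 2, 3 or 4. A passage is one round of detaching and replating the culture. The labels do not name the knocked-out gene. The genotype was taken from each library's title. The separate genotype tag reads WT for the KO-titled libraries of passages 3 and 4, and a fit that follows the tag is among the alternatives. With 1 library per genotype and passage, and no statement of how many embryos or cultures were used, the 3 passages of a genotype may come from 1 culture, so each p-value measures only the spread between these libraries.

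Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39 and quantified with RSEM against mouse genome build GRCm38. The RSEM version, the aligner settings, the annotation release and whether reads were assigned by strand are not given in the sources used here. The deposited table of each library holds expected counts. RSEM makes these by dividing ambiguous reads among genes in proportion to the model's estimates, so that 12.0% to 15.8% of the values were not whole numbers. The same deposited tables hold TPM values (transcript abundances that the authors' RSEM run scaled for length and to a fixed total per library), FPKM values (fragment counts scaled by length and depth, not used in a test) and effective lengths. Because ambiguous reads were shared out by a model and strand handling is unknown, near-identical copies, overlapping genes and antisense genes have uncertain counts.

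The tables list 55487 Ensembl genes, of which 55227 (99.5%) matched GENCODE release M21 of GRCm38 and took their symbols, biotypes and coordinates from it. The other 260 held 0.442% to 0.683% of the counts of a library. Library totals ran from 24853121 to 67760880 expected counts. A count of 0 allows up to 3 counts of the total, which is between 0.0431 and 0.124 CPM (counts scaled to a common library size by TMM). These limits cover counting error only. No 2 libraries held the same values, and chi-square per degree of freedom between pairs of libraries was 37.9 or more. For each gene the percentage of the 64-base words of its transcripts that also occur in transcripts of another gene was computed, and a gene with 25% or more is described as sharing sequence. This measure and its bound were chosen after seeing the data.

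Expected counts were rounded to whole numbers, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, 2-sided) in R 4.3.3, after a filter on low counts by genotype (minimum count 10) that left 16603 genes. Calls used a Benjamini-Hochberg adjusted p under 0.05. The genotype fit held genotype alone (4 residual degrees of freedom). The passage fit tested a linear slope per passage with genotype as a covariate (3 residual degrees of freedom). The interaction fit tested the difference between the genotypes' slopes (2 residual degrees of freedom). CPM values are given as mean ± SD. Fold changes are log2 with their standard errors (SE), and those per passage are changes for each step of 1 passage.

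Before the data were examined, 37 gene lists were fixed. They were the genes named in the series title with TSC complex and p53 genes, mTOR regulators, glycolysis and HIF-1 targets, the pentose phosphate pathway, cholesterol synthesis, fatty acid synthesis, ATF4 targets and tRNA synthetases. Further lists were lysosome and TFEB targets, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, S phase, G2/M phase, p53 targets and the senescence secretome. Signalling and structure lists were chemokines, chemokine receptors, STAT6 and IL-4 targets, interferon-stimulated genes, NF-kB inflammation, collagen and matrix, contractile genes, fibroblast progenitor markers, growth factors and feedback genes, and positional Hox and limb genes. They also held markers of 8 other cell types (macrophage, endothelial, epithelial, muscle, cartilage and bone, neural, adipocyte and erythroid). The last lists were mitochondrially encoded transcripts (fixed as a check of RNA quality), imprinted genes and sex genes. Of the 37 lists, 34 had 5 or more tested members. These entered camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. The title genes and sex genes were given as values only, and the erythroid list had 0 tested members. For tRNA synthetases 20 of the 38 fixed genes were matched to the deposited tables, and every value of that list rests on those 20. Camera was repeated with an estimated correlation, and fry tested whether a list's genes moved, on balance, one way. List members were also counted with p-values adjusted over the list alone. Printed list medians are of edgeR changes. Under an alternative they are of changes fitted to the log2 values that camera tests, which can differ from these.

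Named genes followed a rule fixed at the same time. It took the title genes always, the 12 largest positive and 12 largest negative genotype changes among called protein-coding genes with a mean log2 CPM of at least 2 and the same direction in all 3 passages. It also took up to 4 called members of lowest p per list, the 5 largest slopes each way for passage with the same direction in both genotypes, up to 5 interaction genes, and the sex genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. The slopes were also limited to a mean log2 CPM of at least 2. Some list members that the rule takes for passage are counted with their lists and not named, and the result of 1 gene is not reported here. Other genes are named with a statement that they were chosen after their values were seen.

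The passage numbers were checked for pairing. Deviations from the genotype means correlated across genes between the WT and KO libraries of the same passage at r = 0.49 for passage 2, 0.14 for passage 3 and 0.42 for passage 4 (across genes, which are not independent replicates). All 3 exceeded the bound of 0.1 set for pairing, so values from a fit with passage as a block are printed where they change a result. The labels give the passage numbers and do not say that libraries of a passage were processed together.

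The results were recomputed with DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a stricter filter (at least 50 counts in 3 libraries), and effective lengths as offsets. Further settings were limma on log2(TPM + 1), omission of each library in turn, the passage block, the genotype tag (1 KO library against 5 WT libraries), fits without chromosomes X and Y, a minimum log2 change of 1, an estimated correlation and fry. Fits without the passage 2 libraries, without sequence-sharing genes, and with the block joined to either that omission or DESeq2 size factors were added after seeing the data. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 joined the tables and drew the plots.

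Each fit was tested on simulated data with the real genes' means, library sizes and dispersions over 16603 genes, 200 of them changed. For the genotype comparison edgeR recovered 10.4% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 74.2% of those changed 4-fold, with 6 false calls. For the passage trend it recovered 65.7%, 88.1% and 100% for the same changes per passage, with 14 false calls. For the interaction it recovered 16.4%, 62.7% and 90.9%, with 16 false calls. A simulated shift of -0.5 in the collagen and matrix list was called by camera for genotype and for passage, with 0 other lists called each time. The simulated genes were drawn independently, whereas the estimated correlation between members of the real ribosome biogenesis list was 0.79 for genotype. The 0 is therefore no measure of false list calls in the real data. The simulated libraries were also independent, with no effect of culture or of passage beyond the simulated changes. The recovered shares and false gene calls therefore hold for such data only and do not measure errors among the real calls.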

Results

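RNA-seq of 6 libraries of mouse embryonic fibroblasts compared WT with KO cultures at passages 2, 3 and 4, with 1 library for each genotype and passage. The series title places the cells in a study of mTORC1 signalling, the CCL24-CCR3 chemokine pathway and granulomas. The WT libraries held 42335628, 41933793 and 24853121 expected counts at passages 2, 3 and 4, and the KO libraries held 27361852, 67760880 and 30473493. The first principal component carried 40% of the variance and placed the 3 WT libraries on one side and the 3 KO libraries on the other. The second carried 32.6% and ordered the libraries by passage within each genotype.

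None of the genes tied to the series title that could be tested was called between genotypes. Small changes may be missed, since edgeR recovered 10.4% of simulated 1.5-fold genotype changes. Tsc2 (ENSMUSG00000002496, GRCm38 chromosome 17, 24595816 to 24632630), which encodes tuberin, an inhibitor of mTORC1, had 90.4 ± 8.76 CPM in WT and 83.7 ± 1.63 CPM in KO (SD, n = 3, log2 -0.11 ± 0.10 SE, edgeR adjusted p = 0.564). Its partner Tsc1 had 44.3 ± 4.97 and 48.5 ± 2.33 CPM (log2 0.13, adjusted p = 0.552), and the third subunit Tbc1d7 had a log2 change of 0.14 (adjusted p = 0.596). Rheb, the GTPase that activates mTORC1, had 67.9 ± 6.66 and 82.1 ± 0.925 CPM (log2 0.27, adjusted p = 0.17). Mtor (log2 0.08), Rptor (log2 0.03) and Trp53 (log2 0.40, adjusted p = 0.238) were also not called. Thus 0 of 7 tested genes of this list passed by edgeR, and none passed with the passage block. The deletion of part of a gene can leave its transcripts in place, so these totals do not check a label. Ccl24 had 0 counts in all 6 libraries, a level under 0.0431 to 0.124 CPM. Its receptor gene Ccr3 had 1 count in the KO library of passage 3, 3 counts in the KO library of passage 4 and 0 in the other 4, too few for a comparison at this depth.

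Transcripts that differ between the sexes separated the genotypes completely. Xist, the RNA that coats the inactive X chromosome, had 516 ± 85.9 CPM in the KO libraries and 5, 12 and 5 counts in the WT libraries of passages 2, 3 and 4 (edgeR adjusted p = 1.09e-05). The Y-linked genes went the other way. Ddx3y had 82.6 ± 8.01 CPM in WT and 25 counts over the 3 KO libraries, Eif2s3y had 40.7 ± 1.34 CPM and 8 counts, Kdm5d had 28.7 ± 1.06 CPM and 4 counts, and Uty had 29.1 ± 2.50 CPM and 9 counts, with adjusted p of 0.0066, 0.0021, 0.000805 and 0.00479. These genes divided the libraries as the titles do in 6 of 6 cases and as the genotype tag does in 4 of 6. Genotype and sex were therefore fully confounded, and no difference between WT and KO reported here can be assigned to one of them.

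**Figure D1:**
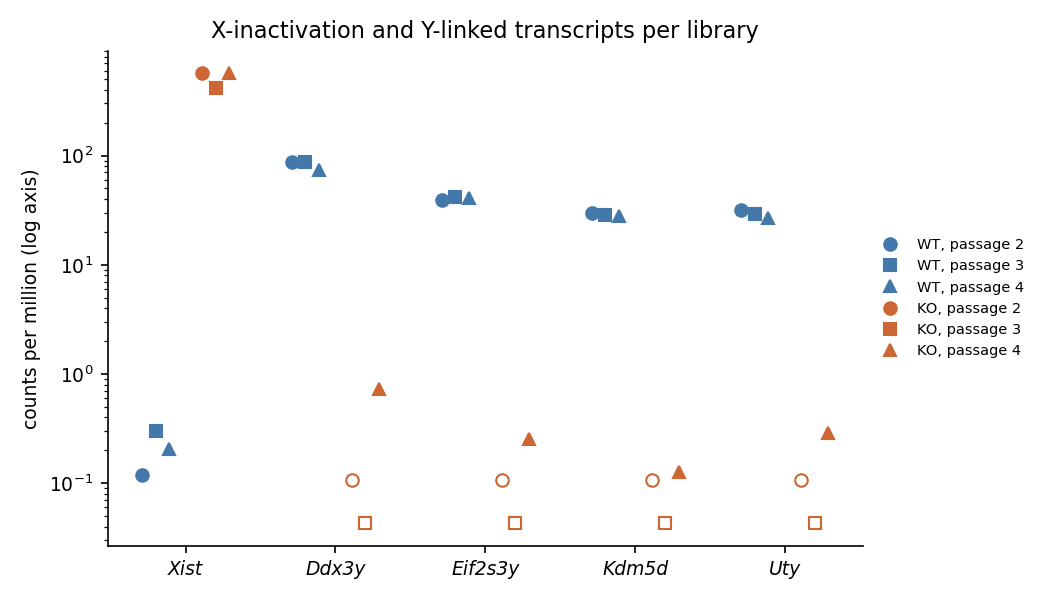
CPM on a log axis of Xist and 4 Y-linked genes in each library, with colour for genotype, symbol shape for passage and open symbols for values under 3 counts, drawn at the level of 3 counts. Xist lay above 400 CPM in the KO libraries only, and each Y-linked gene lay above 20 CPM in the WT libraries only.

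The comparison of genotypes asks which transcripts differed between KO and WT fibroblasts. The genes with the largest changes were taken from called protein-coding genes with a mean log2 CPM of at least 2 and the same direction in all 3 passages. Among the increases, Hmga1, a chromatin-binding high-mobility-group protein (ENSMUSG00000046711, chromosome 17, 27556497 to 27563674), rose from 24.0 ± 1.54 to 144 ± 40.3 CPM (log2 2.59 ± 0.22 SE, adjusted p = 0.00315), with 50.3% of its words shared with other genes and so an uncertain count. Its log2 change was 1.81 with effective lengths as offsets (adjusted p = 0.0138) and 1.86 on the log2(TPM + 1) scale (adjusted p = 0.00456). Acta1, the skeletal muscle actin, rose from 8.5 ± 2.56 to 50.2 ± 31.5 CPM (log2 2.57, adjusted p = 0.0391), and without the KO library of passage 3 its log2 change was 1.92 (adjusted p = 0.0531). Ankrd1, an ankyrin-repeat protein of muscle and a target of YAP, rose from 26.2 ± 6.06 to 77.8 ± 4.39 CPM (log2 1.58, adjusted p = 0.00757). Tm4sf1, a membrane protein of the tetraspanin-like family, rose from 51.5 ± 3.50 to 161 ± 49.4 CPM (log2 1.65, adjusted p = 0.0187). F2rl1, which encodes protease-activated receptor 2 (log2 1.78), the membrane protein gene Nipal1 (log2 1.71), the endothelial lipase gene Lipg (log2 1.58), the transcription factor gene Tfec (log2 1.57), the fatty acid binding protein gene Fabp3 (log2 1.57, 26% of words shared) and the X-linked MAP kinase phosphatase gene Dusp9 (log2 1.53) rose with adjusted p from 0.015 to 0.0382. The remaining genes of this group, Gm3591 on chromosome 14 (9.231, 8.151 and 12.72 CPM in KO and 0.1418, 0 and 0 in WT at passages 2, 3 and 4, adjusted p = 0.00594) and Gm21887 on chromosome X (log2 1.71, adjusted p = 0.0155), shared 90.7% and 57.9% of their words and are uncertain. Each of these genes was higher in KO in all 3 passages.

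Apart from the Y-linked genes, 8 genes had the largest decreases under the same limits. Egfl6, an X-linked matrix protein gene (ENSMUSG00000000402, chromosome X, 166523007 to 166585720), fell from 80.1 ± 31.1 to 4.92 ± 2.37 CPM (log2 -4.05 ± 0.43 SE, adjusted p = 0.00998), with a log2 change of -4.73 without the passage 2 libraries (adjusted p = 0.0084). Ccn3, a matricellular protein gene, fell from 151 ± 6.49 to 29.1 ± 9.84 CPM (log2 -2.38, adjusted p = 0.00979). Cttnbp2, which encodes a cortactin-binding protein, fell from 24.0 ± 5.12 to 4.84 ± 0.674 CPM (log2 -2.32, adjusted p = 0.00301). The matrix protein genes Podn (log2 -2.33), Abi3bp (log2 -2.32) and Tnn (log2 -2.20), the axon guidance gene Draxin (log2 -2.33) and Kcp (log2 -2.10), whose product binds BMP ligands, fell with adjusted p from 0.0155 to 0.042. On the log2(TPM + 1) scale, which understates the change of low genes, Cttnbp2 changed by -1.56 (adjusted p = 0.00845), while Draxin (-1.15, adjusted p = 0.075) and Kcp (-1.17, adjusted p = 0.0631) were not called. Each of these genes was lower in KO in all 3 passages.

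In all, 412 of 16603 genes passed the edgeR test, 155 higher and 257 lower in KO, and 227 of them changed at least 2-fold. Of the 412, 385 were autosomal, 21 lay on chromosome X and 6 on chromosome Y. With passage as a block 1835 genes passed (778 higher, 1057 lower), among them all 412, each with the same sign. Other settings moved the count to 1661 (DESeq2), 846 (no filter), 191 (TPM, 98 higher and 93 lower), 0 (genotype tag, which sets 1 KO library against 5 WT), 48 (minimum log2 change of 1) and 70 (without the passage 2 libraries). Leaving out the WT library of passage 2, 3 or 4 gave 150, 47 or 860 genes and leaving out the KO library gave 205, 44 or 234. Of the 48 genes taken by the rule for named genes that passed, 9 did so in all 6 of these fits (Xist, the 4 Y-linked genes, Hmga1, Gm3591, Cttnbp2 and Mfap4). Of the 48, 34 lost their call without the passage 2 libraries and 38 with the minimum change. TPM values, as log2(TPM + 1), ended 13 calls (Draxin, Kcp, Acacb, Pycr1, Atp6v1c1, Cycs, Igfbp5, Col5a1, Tpm1, Itga5, Igf1, Hoxd8 and Flt1). With effective lengths 5 calls ended (Acacb, Atp6v1c1, Itga5, Igf1 and Flt1), and without a filter 3 (Acta1, Abi3bp and Tnn). F2rl1 lost it by limma-voom and Acacb with the stricter filter.

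Genes of the collagen and matrix list were lower in KO as a group. Of 47 measured members 12 fell, 0 rose and 35 did not pass, with a median log2 change of -0.53 (camera adjusted p = 1.5e-10, adjusted p = 0.497 with an estimated correlation, fry adjusted p = 0.0214, and 0.103 with the block). Mfap4, a microfibril protein gene (ENSMUSG00000042436, chromosome 11, 61485431 to 61488900), fell from 158 ± 32.1 to 45.7 ± 7.76 CPM (log2 -1.79 ± 0.18 SE, adjusted p = 0.00757). Col6a2 fell from 719 ± 29.0 to 311 ± 47.8 CPM (log2 -1.21), Col6a1 from 1020 ± 71.3 to 469 ± 86.8 CPM (log2 -1.12) and Col5a1 from 4160 ± 328 to 2110 ± 195 CPM (log2 -0.98), with adjusted p of 0.00979, 0.0161 and 0.0155. The main fibrillar collagen genes Col1a1 (log2 -0.95), Col1a2 (log2 -1.09) and Col3a1 (log2 -1.61) were among the 12 and were named after their values were seen. Adjusted over the list alone, 23 members fell and 1 rose, and with the passage block 28 fell and 1 rose over all genes. Macrophage markers, which had a median of -0.67 in KO, and mitochondrially encoded transcripts, at 0.41, also differed between the genotypes, the former only with the block (adjusted p = 6.7e-06) and the latter with it (adjusted p = 0.0111) and without it (adjusted p = 0.0134). Both had adjusted p = 0.685 with an estimated correlation and the block, and the latter had adjusted p = 0.863 without the block. Without the WT library of passage 2 the macrophage median was 0.06 (camera adjusted p = 0.915).

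Contractile genes moved the other way. Of 20 members 3 rose and 0 fell, with a median of 0.41 (camera adjusted p = 8.63e-06, adjusted p = 0.766 with an estimated correlation, fry adjusted p = 0.0887), and 6 rose adjusted over the list alone. The smooth muscle actin gene Actg2 rose from 56.8 ± 7.36 to 145 ± 28.1 CPM (log2 1.35 ± 0.17 SE, adjusted p = 0.014). The tropomyosin gene Tpm1 rose from 1020 ± 111 to 1620 ± 113 CPM (log2 0.66, adjusted p = 0.0399) and the fibronectin receptor gene Itga5 from 496 ± 31.9 to 715 ± 38.3 CPM (log2 0.53, adjusted p = 0.0439). With the block 9 members rose. Muscle markers, which share some transcripts with this list, had a median of 0.47 (camera adjusted p = 0.0926, and 0.0268 with the block, where adjusted p = 0.685 with an estimated correlation).

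**Figure D2:**
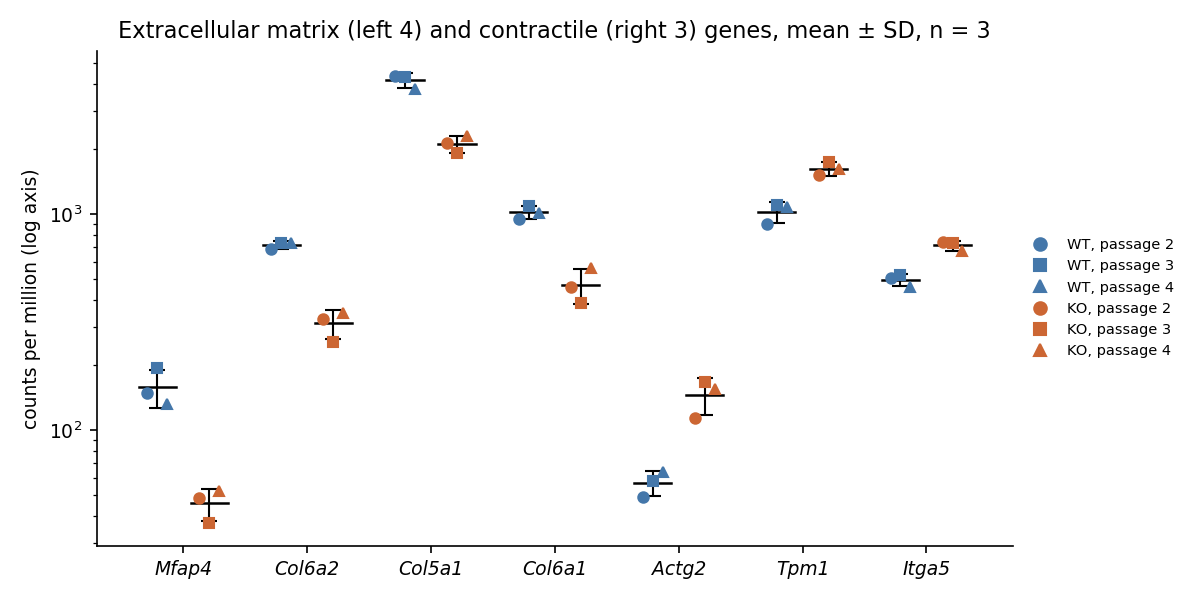
CPM on a log axis of 4 matrix and 3 contractile genes, where each symbol is 1 library, coloured by genotype and shaped by passage, with the mean and SD of 3 libraries in black. The KO libraries lie below every WT library for the matrix genes and above every WT library for the contractile genes, such as Mfap4 at 45.7 against 158 CPM and Actg2 at 145 against 56.8 CPM on average.

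Genes whose products build ribosomes were higher in KO as a list. The ribosome biogenesis list had a median log2 change of 0.61 over 46 members (camera adjusted p = 1.18e-16, adjusted p = 0.766 with an estimated correlation, fry adjusted p = 0.196). By edgeR 0 of 46 passed over all genes (Rrp9, named after its value was seen, had a log2 change of 1.03 and adjusted p = 0.0518), 40 rose adjusted over the list alone and 26 rose with the passage block. Within passages 2, 3 and 4 the median was 0.67, 0.97 and 0.22. For the mRNAs of ribosomal proteins themselves the list did not pass (65 members, 0 called and 1 rising with the block, median -0.08, camera adjusted p = 0.16).

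Other lists past the camera threshold had small medians. Those higher in KO were mitochondrially encoded transcripts (median 0.41, 0 of 13 called), the pentose phosphate pathway (0.28, 0 of 10), S phase genes (0.26, 0 of 38), tRNA synthetases (0.20, 0 of 20) and oxidative phosphorylation (0.09, 1 of 47). Cycs, the cytochrome c gene, was the 1 that rose (log2 0.80). The tRNA synthetase values cover only the 20 matched genes of the 38 fixed for that list. Cholesterol synthesis was lower (-0.24, 0 of 25). Their adjusted p by camera were 0.0134, 0.00823, 0.0134, 0.00365, 0.0158 and 0.00806 in that order. With an estimated correlation the adjusted p was 0.497 for the pentose phosphate pathway and 0.863 for each of the others. By fry the adjusted p in the same order were 0.629, 0.0214, 0.757, 0.629, 0.723 and 0.561. With the passage block 2 mitochondrially encoded transcripts, 2 pentose phosphate genes, 1 S phase gene, 0 tRNA synthetases and 1 oxidative phosphorylation gene rose, and 3 cholesterol synthesis genes fell. Markers of macrophages had a median of -0.67 in KO (0 of 19 called, camera adjusted p = 0.155). With the passage block 5 fell (Adgre1, Csf1r, Ptprc, Itgam and Ctss, named after their values were seen) and the list passed (adjusted p = 6.7e-06, adjusted p = 0.685 with an estimated correlation). Without the WT library of passage 2 the macrophage median was 0.06 (adjusted p = 0.915 without the block). Oxidative phosphorylation was lost without the WT (median -0.01, adjusted p = 0.571) or KO library of passage 2 (0.02, adjusted p = 0.39), and without both its median was -0.07 (adjusted p = 0.38). S phase genes were lost without the WT library of passage 3 or 4 (adjusted p = 0.0677 and 0.119) or the KO library of passage 2 or 3 (0.331 and 0.0941). Cholesterol synthesis was lost without WT passage 3 or KO passage 4 (0.0677 and 0.128), tRNA synthetases without WT passage 3 (0.126), and mitochondrially encoded transcripts without WT passage 4 (0.21) or without sequence-sharing genes (0.0648).

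**Figure D3:**
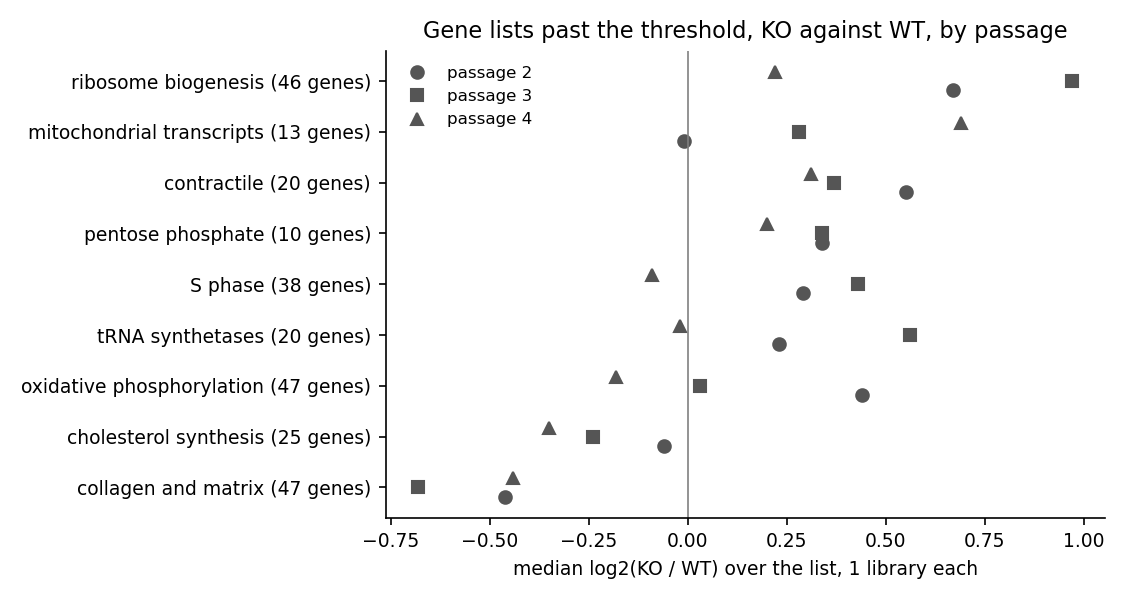
Median log2 ratio of KO to WT over the members of the 9 gene lists past the threshold, with 1 symbol per passage, each from 1 WT and 1 KO library. Collagen and matrix genes lie below 0 and ribosome biogenesis, contractile and pentose phosphate genes above 0 at all 3 passages, whereas oxidative phosphorylation ran from 0.44 at passage 2 to -0.18 at passage 4.

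Several signalling genes changed within lists that did not pass. Among growth factors and feedback genes 2 rose and 2 fell of 29. The MAP kinase response genes Dusp5 (log2 1.28) and Fosl1 (log2 1.14) rose. Pdgfra, a receptor that marks fibroblasts (log2 -1.51, 761 ± 185 to 268 ± 14.7 CPM, also the 1 of 19 fibroblast progenitor markers that fell), and Igf1 (log2 -1.14) fell. In the senescence secretome list 2 of 37 rose, the urokinase gene Plau (log2 1.02) and its receptor gene Plaur (log2 0.81). In it 2 fell, the neutrophil chemokine gene Cxcl1 (log2 -1.41, also the 1 of 29 NF-kB genes that fell) and Igfbp5 (log2 -0.56). Of 26 chemokine genes 2 fell, Cxcl1 and Cxcl14 (log2 -1.53). Single members fell in the lists of fatty acid synthesis (Acacb, log2 -1.05, 1 of 15), ATF4 targets (Pycr1, log2 -0.90, 1 of 36), positional genes (Hoxd8, log2 -0.74, 1 of 37) and endothelial markers (Flt1, log2 -1.02, 1 of 13). Single members rose among lysosomal genes (Atp6v1c1, log2 0.74, 1 of 45), muscle markers (Acta1, 1 of 9) and cartilage and bone markers (Col2a1, 0.585 ± 0.350 to 3.72 ± 1.19 CPM, 1 of 10). Their adjusted p by edgeR lay between 0.0107 and 0.0453. On the log2(TPM + 1) scale Acacb changed by -0.45 (adjusted p = 0.303) and Col2a1 by 0.99 (adjusted p = 0.0185). Without the passage 2 libraries Col2a1 had a log2 change of 3.27 (adjusted p = 0.0763). Without the KO library of passage 3 Acta1 had a log2 change of 1.92 (adjusted p = 0.0531). With the passage block 6 growth factor and feedback genes rose and 7 fell, and 7 and 7 genes of the senescence secretome did. In the same order the counts were 1 and 6 for chemokines, 1 and 2 for NF-kB genes, 0 and 4 for fibroblast progenitor markers, 0 and 4 for fatty acid synthesis and 1 and 2 for ATF4 targets. They were 2 and 5 for positional genes, 0 and 1 for endothelial markers, 6 and 2 for lysosomal genes, 2 and 0 for muscle markers and 2 and 2 for cartilage and bone markers.

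Without the passage block no member passed in the lists of mTOR regulators (47 tested, median 0.07, camera adjusted p = 0.496), glycolysis (37, -0.20, adjusted p = 0.13), G2/M phase (36, 0.01, adjusted p = 0.976), p53 targets (36, 0.18, adjusted p = 0.188), and interferon-stimulated genes (40, -0.17, adjusted p = 0.0676). The same held for STAT6 and IL-4 targets (17, -0.38, adjusted p = 0.263), chemokine receptors (11, -0.67, adjusted p = 0.0676), imprinted genes (22, -0.20, adjusted p = 0.103), epithelial markers (9, 0.27, adjusted p = 0.0926), neural markers (10, 0.05, adjusted p = 0.425) and adipocyte markers (8, -0.11, adjusted p = 0.61). With the block 3 mTOR regulators rose and 2 fell, and the counts rising and falling were 1 and 5 for glycolysis, 0 and 0 for G2/M phase, 7 and 3 for p53 targets and 0 and 6 for interferon-stimulated genes. They were 1 and 3 for STAT6 and IL-4 targets, 0 and 1 for chemokine receptors, 1 and 6 for imprinted genes, 2 and 0 for epithelial, 1 and 0 for neural and 0 and 1 for adipocyte markers. Of the 34 lists 9 passed camera (14 without the KO library of passage 2), 0 with an estimated correlation and 2 by fry. With the passage block 17 lists passed, of which 0 passed with an estimated correlation and 0 by fry. The 8 added were macrophage, epithelial and muscle markers, fibroblast progenitor markers, interferon-stimulated genes, p53 targets, fatty acid synthesis and glycolysis. Their blocked adjusted p were 6.7e-06, 0.00751, 0.0268, 0.00301, 0.00881, 0.0268, 0.0268 and 0.0464, and each had adjusted p = 0.685 with an estimated correlation.

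The comparison across passages asks which transcripts rose or fell from passage 2 to passage 4 in both genotypes. Among called genes with a mean log2 CPM of at least 2 and the same direction in both genotypes, the largest increases per passage were in Tgtp1, an interferon-induced GTPase gene (log2 1.48 ± 0.08 SE, 79% of words shared and so uncertain), and Ptn, the growth factor pleiotrophin (log2 1.42 ± 0.19 SE, from 178.5 to 972.8 CPM in WT and 52.9 to 477.8 in KO). They were followed by the orphan receptor gene Gpr149 (log2 1.32), Rgs4, a regulator of G-protein signalling (log2 1.16), and the chemokine gene Ccl5 (log2 1.15), and the 5 had adjusted p from 0.000748 to 0.0111. Under the same limits the largest decreases were in Chtf8 (ENSMUSG00000117748, 1 of 2 genes with this symbol, log2 -2.96, 95.7% of words shared and so uncertain), and Hp, which encodes the plasma protein haptoglobin (log2 -2.17 ± 0.20 SE, from 163.9 to 7.367 CPM in WT and 150 to 7.312 in KO). Next were the haem-binding hemopexin gene Hpx (log2 -2.04), the thrombospondin gene Thbs4 (log2 -1.91) and the lipid droplet gene Plin4 (log2 -1.79), and the 5 had adjusted p from 0.00319 to 0.0208. Chtf8 had a slope of -1.46 with effective lengths as offsets (adjusted p = 0.023), -2.09 without the WT library of passage 2 (adjusted p = 0.026) and -1.54 without the passage 2 libraries (adjusted p = 0.276). Without the passage 2 libraries the slope was 2.07 for Ptn (adjusted p = 0.0985), -2.81 for Hp (adjusted p = 0.0116), -1.07 for Hpx (adjusted p = 0.305) and -1.18 for Plin4 (adjusted p = 0.189). On the log2(TPM + 1) scale Chtf8, Hpx and Plin4 had slopes of -1.16, -1.45 and -1.15.

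By edgeR 1038 of 16603 genes passed for the linear trend, 461 rising and 577 falling. DESeq2 gave 1709 genes, no filter 2443 and TPM values 608, and without the passage 2 libraries 13 passed. Leaving out the WT library of passage 2, 3 or 4 gave 330, 1261 or 339 genes and leaving out the KO library gave 283, 633 or 248. Of the 100 genes taken by the rule that passed, 39 did so in all 6 of these fits. Without the passage 2 libraries 97 of the 100 lost their call, all but Tgtp1, Hp and Des. That fit held fewer libraries and residual degrees of freedom and spanned passages 3 and 4 only. The lost calls alone therefore cannot show that these trends rest on passage 2. TPM values ended 25 calls, among them those of Hk2, Sgsh, Gaa, Ccne2, Top2a and Acta2. With effective lengths 10 calls ended, among them those of Ccne2, Il6 and Gfap, and by limma-voom 3.

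Markers of other cell types fell with passage in both genotypes. For macrophages 18 of 19 tested markers fell, with a median of -1.27 per passage (camera adjusted p = 4.7e-21, adjusted p = 0.282 with an estimated correlation, fry adjusted p = 0.0075). Adgre1, the F4/80 antigen, went from 40.31 to 3.932 CPM in WT and from 25.06 to 3.243 CPM in KO (log2 -1.58 ± 0.11 SE per passage, edgeR adjusted p = 0.00117). The complement gene C1qa (log2 -1.95), the leukocyte plastin gene Lcp1 (log2 -1.42) and the cathepsin gene Ctss (log2 -1.20) also fell. For adipocytes 7 of 8 fell (median -1.40, camera adjusted p = 2.31e-08, adjusted p = 0.282 with an estimated correlation). The adiponectin gene Adipoq fell from 9.432 to 0.1656 CPM in WT and from 10.85 to 0.3179 CPM in KO (log2 -2.78 ± 0.16 SE, adjusted p = 0.000748), as did Cfd (log2 -2.93), Plin1 (log2 -2.21) and the fatty acid receptor gene Cd36 (log2 -1.65). Endothelial markers fell in 6 of 13 (median -0.79, camera adjusted p = 1.45e-05), including Cdh5 (log2 -2.14) and Pecam1 (log2 -1.84). Epithelial markers fell in 4 of 9 (median -1.08, adjusted p = 3.34e-07), including the keratin genes Krt5 (log2 -3.41) and Krt14 (log2 -2.69). Muscle markers fell in 4 of 9 (median -0.64, adjusted p = 0.0011), including Myh3 (log2 -2.32), and neural markers in 3 of 10 (median -0.43, adjusted p = 0.000443), including Gfap (log2 -1.91). For these 4 lists the adjusted p with an estimated correlation was 0.265, 0.301, 0.289 and 0.289 (fry adjusted p = 0.0075, 0.0337, 0.0337 and 0.0337, and 0.0104 for adipocytes), and the muscle list was lost with the stricter filter (median -0.43, adjusted p = 0.386). At passage 4 the level was under 3 counts for Krt5 in WT and KO, for Krt14 and Myh3 in WT and for Gfap in KO. The size of these slopes is therefore uncertain. Without the KO library of passage 2 the slope of Cdh5 was -2.82 (adjusted p = 0.00869). Without the WT library of passage 2 the slopes of Krt5 and Krt14 were -2.77 (adjusted p = 0.0237) and -1.90 (adjusted p = 0.0367), and without the KO library of passage 4 that of Krt14 was -3.30 (adjusted p = 0.0253). Without the passage 2 libraries, a fit with fewer libraries, no marker named here was called. The unlogged fold change per passage then moved by over 1.5 times for Cfd, Krt5, Krt14 and Gfap (log2 slopes -2.19, -2.47, -1.42 and -2.58). On the log2(TPM + 1) scale the slopes were -1.19 for C1qa, -1.74 for Adipoq, -1.73 for Cfd, -1.11 for Plin1, -0.79 for Cdh5, -0.72 for Pecam1, -1.03 for Krt5, -1.04 for Krt14, -0.37 for Myh3 and -0.41 for Gfap, each still called. Of 10 cartilage and bone markers 0 passed (median -0.15, camera adjusted p = 0.136), and no erythroid marker of the 9 measured was abundant enough to test.

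**Figure D4:**
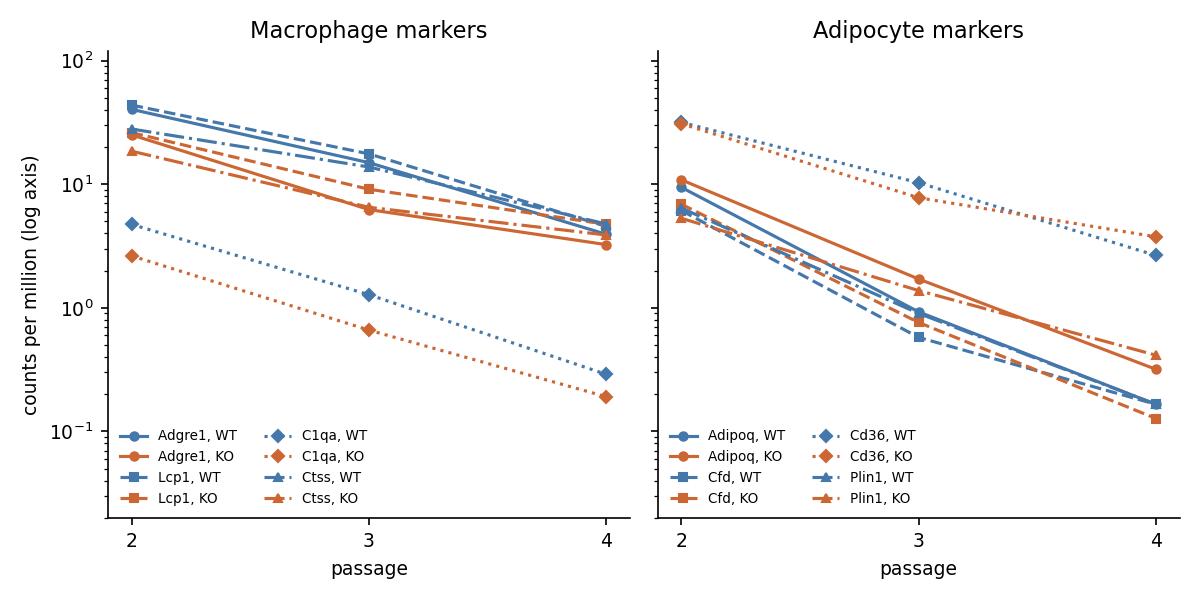
CPM on a log axis of 4 macrophage and 4 adipocyte markers at passages 2, 3 and 4, with 1 library per point and lines joining the passages of a genotype. Each line falls, for example Adipoq from 9.432 to 0.1656 CPM in WT.

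Interferon-stimulated genes rose with passage while macrophage markers fell (median -1.27). Of 40 members 27 rose and 0 fell, 34 adjusted over the list alone, with a median of 0.33 per passage (camera adjusted p = 4.46e-18, adjusted p = 0.265 with an estimated correlation, fry adjusted p = 0.0075). Irf7, a transcription factor of the interferon response, went from 148.5 to 288.9 CPM in WT and from 118.9 to 238.1 CPM in KO (log2 0.49 ± 0.05 SE, adjusted p = 0.00289). Ifit3 (log2 0.63, 45.4% of words shared), Ifit3b (log2 0.71, 39.4% of words shared) and Gbp3 (log2 0.49) also rose. Of 36 p53 targets 20 rose and 0 fell, 25 and 1 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 2.46e-11, adjusted p = 0.265 with an estimated correlation, fry adjusted p = 0.0075). They included the epoxide hydrolase gene Ephx1 (log2 0.78), the receptor gene Eda2r (log2 0.62), Pmaip1, which encodes the pro-apoptotic protein Noxa (log2 0.61), and Inka2 (log2 0.78). Lysosomal genes rose in 8 of 45 (median 0.12, camera adjusted p = 3.07e-05, adjusted p = 0.366 with an estimated correlation, fry adjusted p = 0.0381), including Sgsh (log2 0.40) and Gaa (log2 0.26), which encode lysosomal hydrolases. Contractile genes passed at adjusted p = 0.0443 (adjusted p = 0.846 with an estimated correlation, fry adjusted p = 0.299), with 3 of 20 rising (Myh11, log2 0.70, Acta2, log2 0.35, and Lmod1, log2 0.53) and the intermediate filament gene Des falling (log2 -0.96). The contractile list was lost without the WT library of passage 2 (median 0.01, adjusted p = 0.474), without that of passage 4 (0.08, adjusted p = 0.0836), and with the stricter filter (0.04, adjusted p = 0.0826). It turned to -0.03 without the passage 2 libraries (adjusted p = 0.622). Without the passage 2 libraries the slope of Des was -1.64 (adjusted p = 0.0204).

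Cell cycle and glycolysis genes fell over the same passages as the macrophage (median -1.27) and adipocyte markers (median -1.40). Among S phase genes 8 of 38 fell (median -0.25, camera adjusted p = 4.47e-10), including Uhrf1 (log2 -0.50) and the cyclin gene Ccne2 (log2 -0.42). Among G2/M genes 9 of 36 fell (median -0.26, adjusted p = 6.53e-11), including the proliferation marker Mki67 (380.4 to 222.2 CPM in WT and 345.1 to 174.9 in KO, log2 -0.44 ± 0.06 SE, adjusted p = 0.00782) and the topoisomerase gene Top2a (log2 -0.38). With an estimated correlation the adjusted p of both lists was 0.587, and by fry it was 0.12. Adjusted over the list alone, 23 S phase genes fell, and 25 G2/M genes fell while 1 rose. Glycolysis and HIF-1 targets fell in 11 of 37 (21 adjusted over the list alone, median -0.35, camera adjusted p = 2.46e-11, adjusted p = 0.444 with an estimated correlation, fry adjusted p = 0.082). Those of lowest p were the hexokinase gene Hk2 (log2 -0.42), the pyruvate dehydrogenase kinase gene Pdk1 (log2 -0.58), Pfkl (log2 -0.42) and the lactate transporter gene Slc16a1 (log2 -0.57). NF-kB genes fell in 7 of 29 (median -0.25, camera adjusted p = 0.000894, adjusted p = 0.335 with an estimated correlation, fry adjusted p = 0.0337), including Tnf (log2 -1.61), Cxcl2 (log2 -0.82), Il6 (log2 -0.73) and Bcl3 (log2 -0.65). STAT6 and IL-4 targets fell in 4 of 17 and rose in 1 (median -0.23, camera adjusted p = 0.0299, adjusted p = 0.301 with an estimated correlation, fry adjusted p = 0.0161). The mannose receptor gene Mrc1 fell (log2 -1.62) and Ccl11, the chemokine eotaxin that binds CCR3, rose (log2 0.85, from 20.59 to 96.27 CPM in WT and from 19.98 to 42.51 in KO, adjusted p = 0.0196). The STAT6 list, which shares Mrc1 with the macrophage markers, was lost without the KO library of passage 4 (adjusted p = 0.0605) and without the passage 2 libraries (median -0.12, adjusted p = 0.0731). The slopes of Tnf and Mrc1 on the log2(TPM + 1) scale were -0.93 and -0.70, and that of Tnf without the passage 2 libraries was -2.26 (adjusted p = 0.139).

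**Figure D5:**
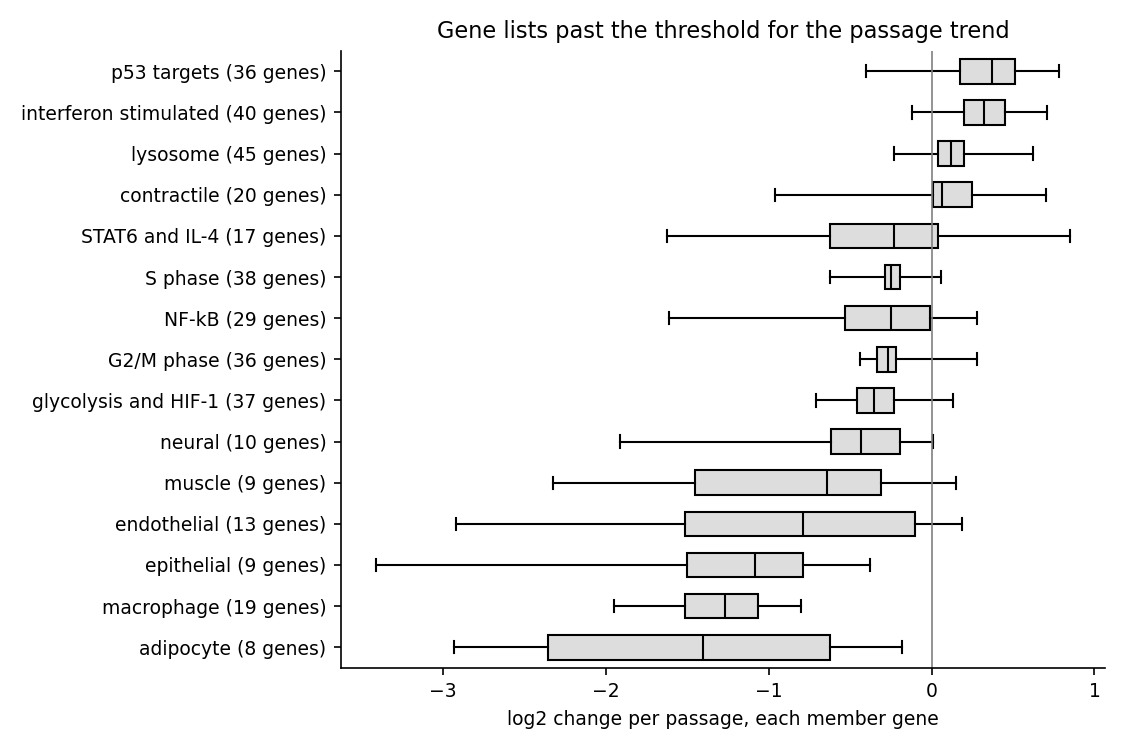
Log2 change per passage of each tested member gene in the 15 lists past the threshold, with boxes at the quartiles, the median as a line and whiskers to the lowest and highest member. Medians run from -1.40 for adipocyte markers to 0.37 for p53 targets.

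The other lists did not pass as groups. Chemokine genes went both ways, 5 rising and 7 falling of 26 (median 0.04, mean -0.20, camera adjusted p = 0.988), with Ccl5 rising and Ccl9 (log2 -1.28) and Ccl12 (log2 -1.56) falling. Of the chemokine receptor genes Cxcr4 (log2 -1.54) and Ccr1 (log2 -1.37) fell, and the list of 11 did not pass (camera adjusted p = 0.523). On the log2(TPM + 1) scale the slopes of Cxcr4 and Ccr1 were -0.72 and -0.45, and without the passage 2 libraries that of Ccl12 was -0.96 (adjusted p = 0.524). The senescence secretome list had 7 rising, including the cell cycle inhibitor gene Cdkn2a (log2 0.74, from 7.187 to 21.44 CPM in WT and 8.798 to 22.76 in KO, adjusted p = 0.00237), and 4 falling, including Igfbp4 (log2 -0.82), of 37 (adjusted p = 0.732). The collagen and matrix list had 2 rising and 5 falling of 47 (median 0.00, adjusted p = 0.695), with Col15a1 (log2 -1.19) and Col5a3 (log2 -0.75) falling and Timp2 rising (log2 0.40). Genes called rising and falling numbered 4 and 5 of 29 growth factors and feedback genes (adjusted p = 0.404), 3 and 3 of 19 fibroblast progenitor markers (adjusted p = 0.693), 3 and 2 of 47 mTOR regulators (adjusted p = 0.259), 0 and 2 of 36 ATF4 targets (adjusted p = 0.454) and 0 and 1 of 15 fatty acid synthesis genes (Scd1, log2 -0.68, list adjusted p = 0.111). In the lists of ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, tRNA synthetases, cholesterol synthesis, the pentose phosphate pathway and mitochondrially encoded transcripts 0 genes passed (camera adjusted p = 0.0599, 0.461, 0.576, 0.624, 0.948, 0.978 and 0.24). Of the 34 lists 15 passed camera, 4 rising and 11 falling, 0 passed with an estimated correlation and 11 passed by fry.

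The interaction of genotype and passage asks whether the KO to WT difference changed between passages. By edgeR 0 of 16603 genes passed, with 1137 at an unadjusted p under 0.05. DESeq2 called 83 genes (19 higher and 64 lower slopes in KO), limma-voom 0, the fit without a filter 289 and limma on TPM values 1. Leaving out the KO library of passage 2, 3 or 4 gave 1, 11 or 8 genes, and leaving out any WT library gave 0.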

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

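The list test of the interaction was chosen after the data were seen. For 12 of 34 lists the change per passage differed between genotypes by camera with the preset correlation, 9 with a lower slope in KO and 3 with a higher one, although edgeR called 0 genes over all genes tested (1137 at an unadjusted p under 0.05, DESeq2 83, limma-voom 0). With an estimated correlation 0 of 34 passed (lowest adjusted p = 0.764), and 0 passed by fry. The values are the median, over each list, of the KO slope minus the WT slope in log2 per passage.

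Ribosomal protein genes had a median of -0.42 (camera adjusted p = 3.33e-30), and 53 of 65 passed adjusted over the list alone. Their median log2 ratio of KO to WT was 0.38 at passage 2, -0.21 at passage 3 and -0.42 at passage 4, each from 1 library per genotype. Oxidative phosphorylation genes had a median of -0.32 (adjusted p = 2.45e-16) and ribosome biogenesis genes -0.24 (adjusted p = 5.71e-06). Mitochondrially encoded transcripts went the other way at 0.46 (adjusted p = 0.000132), with 7 of 13 passing adjusted over the list alone. That list was fixed as a check of RNA quality, and whether RNA quality lies behind its value was not tested. S phase genes had a median of -0.19 (adjusted p = 5.71e-06) and G2/M genes -0.17 (adjusted p = 0.00124). The ATF4 target list had -0.25 (adjusted p = 0.00249), cholesterol synthesis -0.14 (adjusted p = 0.00527), the senescence secretome -0.19 (adjusted p = 0.00578) and p53 targets -0.1 (adjusted p = 0.0327). Epithelial markers had 0.92 (adjusted p = 0.000928, 9 genes) and chemokine receptors 0.34 (adjusted p = 0.0119, 11 genes).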

How the results depend on the processing

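The alternatives without the passage 2 libraries or without sequence-sharing genes, and the block combined with another choice, were chosen after seeing the data, and the cause of each change below was not tested unless stated. For the genotype comparison (412 genes) the passage block gave 1835 genes, 1771 with DESeq2 size factors and 2321 without sequence-sharing genes, DESeq2 1661, no filter 846, TPM 191, a minimum log2 change of 1 gave 48, and omission of passage 2 gave 70, a fit with fewer libraries. The fit by the genotype tag gave 0, but it sets 1 library against 5 and counts KO-titled libraries as WT, so it says nothing about stability. The 48 genes past the minimum change were a subset of the 412 by construction of that stricter test. Leaving out 1 library gave 44 to 860 genes, in fits with fewer libraries. The settings that stayed within 1.5 times gave 322 to 456 genes. For the passage trend (1038 genes) DESeq2 gave 1709, no filter 2443, TPM 608 and omission of passage 2 gave 13, with 248 to 1261 on leaving out 1 library. For the interaction (0 genes) DESeq2 gave 83, no filter 289 and TPM 1, with 0 to 11 on leaving out 1 library.

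Of the gene lists for genotype (9 past the threshold) the passage block gave 17, TPM 14, fry 2, an estimated correlation 0 and omission of passage 2 gave 14, with 6 to 14 on leaving out 1 library. For passage (15 lists) an estimated correlation gave 0 and fry 11, with 15 to 20 on leaving out 1 library. The block lost 0 of the 48 named genes and 0 of the 9 lists. Collagen and matrix, contractile, ribosome biogenesis and pentose phosphate genes passed in all 6 fits that left out a library for genotype, and 13 of 15 lists did for passage. S phase genes were lost without the KO library of passage 2 or 3 or the WT library of passage 3 or 4 (medians 0.07, 0.18, 0.17 and 0.2), oxidative phosphorylation without either library of passage 2 (0.02 and -0.01), cholesterol synthesis without WT passage 3 or KO passage 4 (-0.14 and -0.13), tRNA synthetases without WT passage 3 (0.1) and mitochondrial transcripts without WT passage 4 (0.31) or sequence-sharing genes (0.35). Per passage the stricter filter ended the calls of contractile (0.04) and muscle genes (-0.43).

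Of lists past the threshold with or without the alternative, the camera direction and the median turned, per passage, for oxidative phosphorylation without the KO library of passage 2 (0.07) or 4 (0.08), and ribosomal proteins without the KO library of passage 2 (0.1). Over the 6 fits these medians ran from -0.14 to 0.08 and -0.22 to 0.1. For cholesterol synthesis per passage the median (-0.02) and the mean (0.01) differ in sign. Its camera direction, which was up, turned down without the WT library of passage 2 (median -0.09) and without the passage 2 libraries (-0.2), and its median ran from -0.09 to 0.07 over the 6 fits. For KO against WT the median of oxidative phosphorylation turned to -0.01 without the WT library of passage 2, while its camera direction did not turn. Over all 34 lists, leaving out 1 library turned 17 medians, of 11 lists, for genotype and 18, of 9 lists, per passage. One was that of macrophage markers for KO against WT (0.06 without the WT library of passage 2). Median, mean and camera direction differed in sign for ATF4 targets, G2/M, positional and adipocyte genes for genotype. The same held per passage for pentose phosphate, cholesterol synthesis, senescence secretome, chemokine, growth factor and mitochondrially encoded genes. None of these lists passed in that comparison. Without the passage 2 libraries oxidative phosphorylation turned to -0.07 for KO against WT, and per passage ATF4 targets to 0.3, tRNA synthetases to 0.3, ribosome biogenesis to 0.23 and contractile genes to -0.03. Of the 48 named genotype genes 17, 35 and 18 lost their call without the KO library of passage 2, 3 or 4 and 24, 36 and 5 without the WT library, and 0 changed sign. A minimum log2 change of 1 lost 38, omission of passage 2 lost 34, TPM 13, effective lengths 5, no filter 3, limma-voom 1 and the stricter filter 1. Of the 100 named passage genes 39, 15 and 47 lost it without the KO library of passage 2, 3 or 4 and 44, 1 and 51 without the WT library, and 0 changed sign. Omission of passage 2, a fit with fewer libraries, lost 97, TPM 25, effective lengths 10 and limma-voom 3.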

Other observations

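The tests of explanations and the splits of the libraries in this part were chosen after the result was seen, except the count of steroid-cell markers, whose interval was added afterwards. Transcripts of the imprinted Igf2 and H19 neighbourhood on chromosome 7 fell together with passage. H19 went from 3503 to 856.3 CPM in WT and from 1614 to 451.5 in KO (log2 -0.96 ± 0.13 SE per passage, edgeR adjusted p = 0.00961), and the growth factor gene Igf2 from 1906 to 266.4 CPM in WT and from 1106 to 157.2 in KO (log2 -1.41 ± 0.08 SE, adjusted p = 0.000748), with 60.7% of its words shared with transcripts of another gene. Of 22 imprinted genes 2 fell and 1 rose, Impact (log2 0.47), and the list did not pass (camera adjusted p = 0.838). Of 37 positional genes 6 rose with passage, those of lowest p being Hoxc6 (log2 0.54), Hoxb9 (0.47), Hoxc9 (0.50) and Hoxb8 (0.47), and 2 fell (camera adjusted p = 0.13 for the list). The limb genes Tbx4 (log2 -0.71, adjusted p = 0.0459) and Pitx1 (log2 -0.52, adjusted p = 0.0493), named after their values were seen, were those 2.

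The KO library of passage 4 held 44 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, 0.772% of the WT mean, against 2 counts in the KO library of passage 2 and 0 in that of passage 3. All 4 genes were seen in it, at 0.458% to 1.08% of the WT library of passage 4.

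The split of the 6 libraries by genotype called 412 genes and the highest other of the 10 splits called 0, and 1 split reached 412. For gene lists the genotype split called 9, the highest other called 18, and 9 splits reached 9. With 10 splits no share under 0.05 can be reached. The splits other than the genotype split that keep a passage together called 13 to 18 lists and differ in their passages, a structure of these samples, and the 3 others that part each passage pair called 6, 9 and 11 lists and 0 genes.

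Collagen and matrix genes were lower in the KO libraries. Library scaling or gene length as the whole source was argued against, since the median log2 change nearest 0 under 3 other scalings was -0.38. A smaller share of fibroblasts in the KO cultures would raise markers of whichever other cells were more frequent, not necessarily of all types. With the passage block 5 macrophage markers fell while 2 epithelial (Krt18 and Krt19) and 2 muscle markers (Des and Acta1) rose. Of 19 fibroblast progenitor markers 4 fell and 0 rose with the block. Which other cells would be more frequent is unknown, so the counts cannot decide this explanation. Without the block, the macrophage median was 0.06 without the WT library of passage 2 and the epithelial median -0.12 without the WT library of passage 4. Embryo sex cannot be told apart from genotype, since the sex genes follow the title in 6 of 6 libraries. The knocked-out gene, embryo sex and differences between single cultures may each contribute. Separating sex from genotype would need libraries of both genotypes from embryos of the same sex. Separating differences between cultures from genotype would need several independent cultures of each genotype.

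Some genes were near 0 in one genotype. Of 58 autosomal genes called at 8-fold or more, 36 were higher in KO and 22 lower, 23 were pseudogenes, and 74.1% shared 25% or more of their words with another gene, against 1423 of 16603 tested genes, so reads divided between near-identical copies are a candidate source of part of the pattern. Embryo sex could act through copies on chromosomes X and Y, and 1.7% (1 gene) had its closest copy there. Only the closest copy of each gene was examined, so further copies on these chromosomes were not tested and this explanation stays undecided. A run of 21 such genes lay between 3049285 and 7568566 on chromosome 14, and all 21 were higher in KO. In a wider stretch, from the start of the chromosome to beyond that run, 31 genes were tested. Different parental strains or copy numbers at this region may be a source and cannot be told apart from genotype, since gene tables hold no genotypes.

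Cyp11a1 and Hsd3b1, enzymes of steroid hormone synthesis that were named after their values were seen, had 275 and 61 counts in the WT libraries against 2 and 1 in the KO libraries. Steroid-producing cells in the WT culture were a hypothesis tested with 12 other marker genes listed beforehand. Of 9 detected, 2 were higher in WT at all 3 passages, Nr5a1 (27 against 1 counts) and Inha (289 against 139), a share of 22.2%. The bound written beforehand, under 50%, was therefore met against this explanation. It is left open because 5 of the 9 markers had under 30 counts and the share is imprecise. The exact 95% interval of the share runs from 2.8% to 60.0%. That interval was computed after the result was seen and treats the markers as independent. Star, the most abundant marker, had 518 counts in WT and 628 in KO, and Cyp11b1 had 17 and 115. These are raw counts over libraries of unequal depth. After scaling for depth Star was higher in WT at 2 of 3 passages and Cyp11b1 at 0 of 3.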
